A study of Homo sapiens with 5 samples.

How the data were processed

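RNA was extracted with Trizol and messenger RNA was enriched with oligo-dT beads, per the labels' protocols. The submitters' processing notes name FastQC 0.11.8, Trim Galore 0.6.1, STAR 2.5.0a and HTSeq, the last without a version. The deposited table holds raw counts per gene, with whole numbers whose totals differ between libraries, and a gene length column. The notes name a mouse genome build, while the table holds human Ensembl identifiers: the positions of 58724 of 58735 genes equal those of GENCODE 29 on GRCh38, and the other 11 differ. Positions are given on GRCh38 as in the table. The strand setting, the treatment of reads with several matches and the read length are not given in the sources used here, so overlapping and antisense genes cannot be told apart with certainty and near-identical genes may have lost or shared reads. Genes whose exons lie within another gene's had few counts: of 232 protein-coding genes wholly covered by exons of another gene on the same strand, 230 had a mean count under 2, as had all 17 so covered on the opposite strand, against 3770 of 11097 without any such overlap. The macrophage marker CD68, with 85.8% of its exonic bases shared, had 24 counts over the 5 libraries and was not tested.

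Libraries were assigned to groups by their titles and the series design: 3 with ox-LDL alone and 2 with ox-LDL and MLN4924, all at 48 h. Total counts were 16171049 to 17744833 per library. Genes were kept with edgeR's filterByExpr given the groups, which left 15558 genes with 99.9% of the counts. Counts were scaled with TMM factors (1.06 for each ox-LDL library, 0.886 and 0.940 for the MLN4924 libraries) and fitted with edgeR 4.0.16 in R 4.3.3 by the robust quasi-likelihood method with the group as the only term. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The biological coefficient of variation was 8.95%. Normalized CPM were computed from the deposited counts with the TMM-scaled totals. Levels are means ± SD; intervals of the counts themselves were not used, since nearly all named genes had over 10 counts in each group.

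Before the data were examined, 22 gene lists, the rule for named genes, the design and the alternatives listed first below were fixed. Lists with at least 3 tested genes (21 of 22) were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided, adjusted over the lists. With the correlation estimated per list, 0 lists passed, and the adjusted p is given beside each call. In that setting camera's p-value also rests on the residual degrees of freedom, which are few with 5 libraries. Not passing there therefore does not show that a list did not move. The fry test, which asks whether a list's genes move one way and does not compare them with other genes, passed 16 lists. Where a symbol had several identifiers the one with most counts was used. Named genes were the 6 largest rises and 6 largest falls among called genes with a mean log2 CPM of at least 3, a proper symbol and no overlap between the groups' libraries; the members with the lowest p in each list holding a called gene (2, or 4 where the list passed); and 8 genes fixed in advance (NAE1, UBA3, NEDD8, CD36, MSR1, ABCA1, ABCG1 and PLIN2). Members of a list named as exceptions to its count, and PPARG, FABP4, NQO1, HSPA5, TNF, CDKN1A, MRC1 and CD163, were named after their values were seen. Some genes that the rule selects are not reported here.

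The tests were checked on simulated data. For the comparison of MLN4924 with ox-LDL against ox-LDL alone, 200 of 15558 genes were changed by known folds in counts drawn from the real libraries' means and sizes: edgeR recovered 53.1% of those changed 1.5-fold, 73.9% of those changed 2-fold and 91.0% of those changed 4-fold, and 7.59% of its calls were false. Both groups were simulated with the same spread, while the real MLN4924 libraries differed more from each other than the ox-LDL libraries did. The 200 changed genes are also far fewer than the 8229 called in the data. These rates of recovery and of false calls may therefore not hold for the real comparison. In a simulation over the same genes with 1 list shifted by 0.5 (log2), camera called that list and 0 others. Genes were drawn independently of each other there, so false list calls from correlated genes were not tested. Estimated correlations in the data were -0.0015 to 0.41 over the lists that passed. Alternatives were other scalings (DESeq2's size factors, upper quartile, library size), no low-count filter or a CPM of at least 1 in at least 2 libraries, DESeq2 1.42.0, limma-voom, edgeR without robust estimation, a threshold of 0.01, the replicate number as a block, each library left out in turn, libraries thinned to the lowest total, an estimated list correlation, fry and a prior count of 0.5. After seeing the data, fits of protein-coding genes only, without mitochondrially encoded genes, with trends in GC content and gene length removed, and with a variance weight for each group were added. Where leaving out a library left 1 in the MLN4924 group, that library was assumed to vary like the ox-LDL libraries. The MLN4924 libraries in fact differed more from each other than the ox-LDL libraries did. The p-values of these fits may therefore be too low and their counts of calls too high.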

Results

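Gene expression was measured by sequencing of poly(A) RNA from THP-1 cells, an established human monocytic leukemia line used as a source of macrophages in culture. The cells had been exposed to oxidized low-density lipoprotein (ox-LDL), the modified lipoprotein that macrophages take up when they turn into lipid-laden foam cells, and were collected 48 h into that transformation. There were 3 libraries from cells given ox-LDL alone and 2 libraries from cells given ox-LDL together with MLN4924. MLN4924 (pevonedistat) inhibits the NEDD8-activating enzyme and so blocks neddylation, the attachment of the ubiquitin-like protein NEDD8 to cullins that switches on cullin-RING ubiquitin ligases. The doses were not given in the sources used here. The deposited table held raw counts for 58735 human genes, of which 30017 had a count in at least 1 library. Total counts were 16171049, 17459111 and 17744833 in the ox-LDL libraries and 16622065 and 16493449 in the MLN4924 libraries. The design implied 1 comparison: ox-LDL with MLN4924 against ox-LDL alone at 48 h. No library came from cells without ox-LDL or from another time. Effects of MLN4924 on foam cell formation therefore cannot be told apart from its effects on the cells in general. Levels below are normalized CPM, the counts scaled to a common library total, as mean ± SD over the 3 ox-LDL and the 2 MLN4924 libraries, and log2 fold changes are MLN4924 with ox-LDL over ox-LDL alone, ± SE. Adjusted p-values for genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

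The expression of a large part of the transcriptome differed with MLN4924. The genes of cell division fell furthest among the gene groups examined, while genes of sterol synthesis, the oxidative stress response governed by NRF2, the hypoxia response and matrix remodelling rose. None of these lists passed when the correlation between genes was estimated (adjusted p = 0.12 for DNA replication to 0.29 for sterol synthesis and hypoxia). The estimate itself was -0.0015 for DNA replication and 0.012 for matrix remodelling, below or close to the preset 0.01. For DNA replication and matrix remodelling, a high correlation was therefore not what removed the call. That setting also rests on few residual degrees of freedom, so not passing in it does not show that a list did not move. The scavenger receptor CD36 and the lipid droplet protein PLIN2 fell 2.59-fold and 2.56-fold, and the inflammatory mediators IL1B and CXCL8 rose 9.23-fold and 9.43-fold. Of 15558 genes tested, 8229 (52.9%) differed at adjusted p under 0.05, 4207 of them higher and 4022 lower with MLN4924. The change was at least 2-fold for 3326 genes, with 1618 higher and 1708 lower, and at least 4-fold for 584 higher and 570 lower genes. The median absolute log2 fold change of the changed genes was 0.82. In 10628 genes (68.3%) the libraries of the 2 groups did not overlap, where chance gives 20%. The split between directions depended on the scaling: 51.1% of the calls were higher with the main scaling, 41.1% with upper-quartile factors, which moved the median of all genes by -0.11, and 32.6% with library size alone, which moved it by -0.22.

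**Figure D1:**
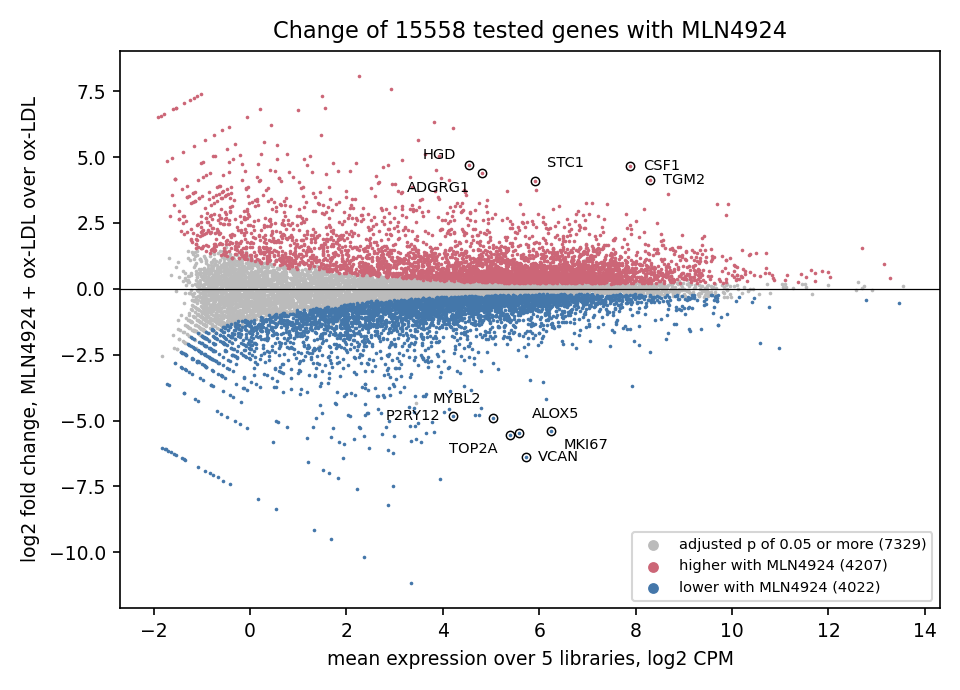
Log2 fold change of MLN4924 with ox-LDL over ox-LDL alone (vertical axis) against mean expression over the 5 libraries in log2 CPM (horizontal axis), with 1 point for each of the 15558 tested genes. The 4207 higher genes are in red, the 4022 lower genes in blue and the rest in gray; circles mark named genes from among the 6 largest rises and the 6 largest falls, and diagonal streaks at low expression are genes with counts at or near 0 in 1 group, whose fitted fold changes are poorly determined.

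Libraries of the same group resembled each other more than libraries of different groups. The correlation of log2 CPM across genes was 0.985 to 0.991 within groups and 0.925 to 0.927 between them, and the first principal component of the 500 most variable genes held 95.8% of their variance, and that of all tested genes 82.9%. The MLN4924 libraries differed more from each other than the ox-LDL libraries did: their chi-square per degree of freedom was 16.5, against 2.71 to 3.65 for the ox-LDL pairs. MLN4924 replicate 1 had 21880 detected genes and MLN4924 replicate 2 had 23515. Cytosolic ribosomal protein genes took 3.46% and 2.66% of the counts in these libraries, and 4.26% to 4.38% in the ox-LDL libraries. No library repeated another within sampling noise. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

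Among called genes with a mean log2 CPM of at least 3 over the 5 libraries and no overlap between the groups, the largest rises were those of HGD, an enzyme of tyrosine breakdown, and CSF1, the growth factor that macrophages depend on. HGD (ENSG00000113924, GRCh38 chromosome 3, 120628173 to 120682571) went from 2.13 ± 0.397 to 54.9 ± 4.80 CPM, a log2 fold change of 4.68 ± 0.15 (adjusted p = 3.18e-10). CSF1 (ENSG00000184371, chromosome 1, 109910242 to 109930992) went from 22.2 ± 1.84 to 560.7 ± 63.9 CPM, a 25.2-fold rise (adjusted p = 6.60e-11). The adhesion receptor ADGRG1 rose 20.8-fold, the transglutaminase TGM2 17.4-fold and the secreted glycoprotein STC1 16.9-fold. The deepest fall by the same rule was that of VCAN (ENSG00000038427, chromosome 5, 83471465 to 83582303), which encodes the matrix proteoglycan versican and went from 87.2 ± 2.87 to 1.03 ± 0.365 CPM (log2 fold change -6.40 ± 0.16, adjusted p = 8.74e-11). ALOX5, the 5-lipoxygenase that starts leukotriene synthesis, fell 44.6-fold from 78.7 ± 4.47 CPM. TOP2A, MKI67 and MYBL2, which are expressed in dividing cells, fell 46.4-fold, 41.9-fold and 29.9-fold, and the ADP receptor gene P2RY12 fell 28.0-fold.

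Genes of sterol synthesis and uptake rose together. Of 23 measured members 21 rose and none fell, with a median log2 fold change of 1.40 (camera adjusted p = 3.55e-10; adjusted p = 0.29 with an estimated correlation). The sterol demethylation enzyme gene MSMO1 went from 35.5 ± 1.68 to 245 ± 26.7 CPM and IDI1, which isomerizes isopentenyl diphosphate, from 36.3 ± 1.58 to 151 ± 0.366 CPM. The sterol carrier gene STARD4 rose 4.05-fold. The members not past the test were LSS, at 0.0088 ± 0.11, and TMEM97, at 0.34 ± 0.18.

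Genes of lipid uptake and storage moved in both directions, with 7 of 22 measured members higher, 9 lower and 6 not past the test. CD36, which binds and internalizes oxidized lipoprotein, fell from 1114 ± 53.2 to 430.1 ± 28.6 CPM (log2 fold change -1.37 ± 0.09, adjusted p = 1.23e-07). MSR1, the class A scavenger receptor, fell from 1183 ± 52.8 to 606 ± 48.8 CPM (-0.97 ± 0.09, adjusted p = 3.01e-06). PLIN2, which coats lipid droplets, fell from 1111 ± 52.0 to 434 ± 34.7 CPM (-1.36 ± 0.10, adjusted p = 1.55e-07). PDK4, a kinase that restrains pyruvate oxidation, fell 27.6-fold, while NPC1, which exports cholesterol from lysosomes, rose 7.25-fold from 31.0 ± 1.01 CPM. The nuclear receptor gene PPARG (-1.30 ± 0.09) and the fatty acid carrier gene FABP4 (-2.05 ± 0.12) also fell. As a set the list did not differ from the other genes (median -0.0093, camera adjusted p = 0.57), and its median was 0.011 with DESeq2's size factors and 0.04 without MLN4924 replicate 2.

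Genes of cholesterol efflux and the LXR response were split, with 5 of 14 higher, 5 lower and 4 not past the test (median -0.13, camera adjusted p = 0.82); with library size alone 5 were higher and 8 lower. The efflux transporter genes went opposite ways. ABCA1, which loads cholesterol onto lipid-poor apolipoprotein, rose from 411 ± 14.3 to 606 ± 70.7 CPM (log2 fold change 0.56 ± 0.09, adjusted p = 0.000250). ABCG1, which passes cholesterol to high-density lipoprotein, fell from 60.7 ± 4.73 to 19.7 ± 1.98 CPM (-1.63 ± 0.11, adjusted p = 1.19e-07). The high-density lipoprotein receptor gene SCARB1 fell 2.52-fold. The remaining rises were those of NR1H2, APOE, APOC1 and SMPDL3A, and the remaining falls those of NR1H3, SREBF1 and PLTP.

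**Figure D2:**
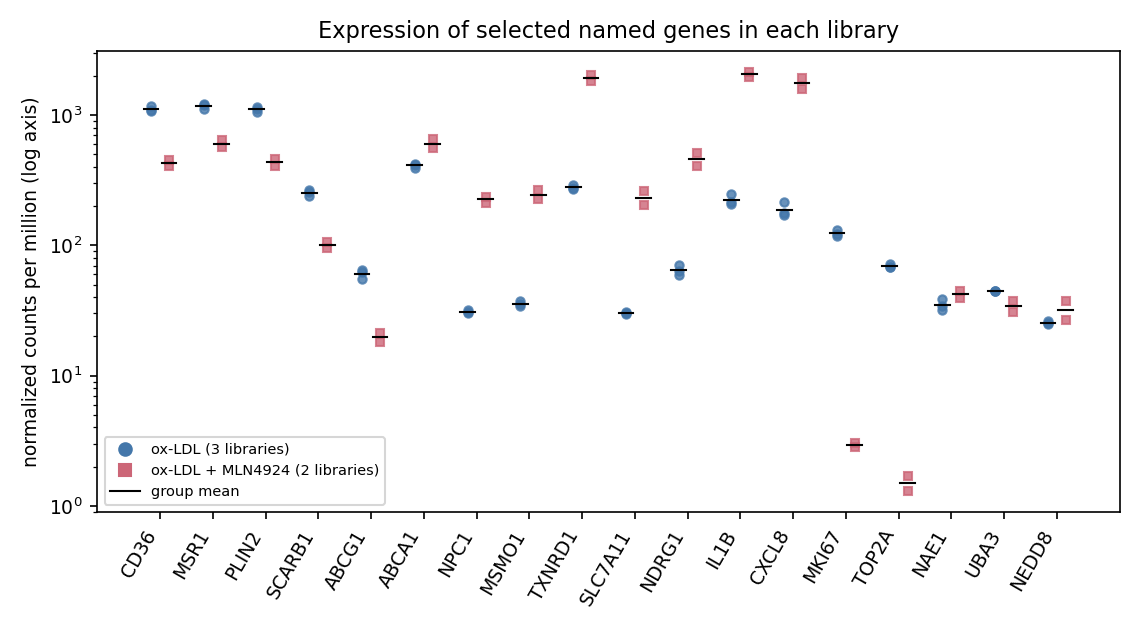
Normalized CPM (vertical log axis) of selected named genes in each library, with circles for the 3 ox-LDL libraries, squares for the 2 MLN4924 libraries and black lines for the group means. CD36, MSR1, PLIN2, SCARB1 and ABCG1 were lower with MLN4924, and ABCA1, NPC1, IL1B and CXCL8 were higher. UBA3 was lower by a smaller amount, and NAE1 and NEDD8 did not pass.

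Genes of the neddylation pathway itself showed mostly small differences. The subunits of the NEDD8-activating enzyme showed log2 fold changes of 0.27 ± 0.11 for NAE1 (ENSG00000159593, chromosome 16, 66802875 to 66873256; 35.0 ± 3.66 and 42.1 ± 3.54 CPM; adjusted p = 0.058) and -0.38 ± 0.10 for UBA3 (ENSG00000144744, chromosome 3, 69054730 to 69080408; 44.6 ± 0.287 and 34.2 ± 4.42 CPM; adjusted p = 0.0071). NEDD8 itself was at 25.6 ± 0.725 and 32.0 ± 7.77 CPM (0.32 ± 0.13, adjusted p = 0.060), and the result depended on the libraries and the processing. It was 0.56 without MLN4924 replicate 2 and 0.05 without MLN4924 replicate 1, and it passed with DESeq2's size factors (adjusted p = 0.048), no low-count filter (0.027) or libraries thinned to the lowest total (0.049). NAE1 was at 0.36 without MLN4924 replicate 2, and it passed the test without ox-LDL replicate 1 (0.34, adjusted p = 0.040) or with DESeq2's size factors (0.29, adjusted p = 0.045). Once a trend with GC content and gene length was removed, NAE1 (0.40, adjusted p = 0.0053) and NEDD8 (0.46, adjusted p = 0.0093) passed and UBA3 did not (-0.22, adjusted p = 0.067). Among 26 neddylation and cullin ligase genes 7 rose and 5 fell (UBA3, RNF7, SENP8, COPS5 and SKP2), and 14 did not pass; adjusted over the list alone, 7 rose and 4 fell. This balance depended on the processing: 4 rose and 11 fell with library size alone, 6 and 6 with upper-quartile factors, and 13 and 2 with the GC content and gene length trend removed. It was 12 and 4 without MLN4924 replicate 2 and 7 and 7 without MLN4924 replicate 1, and 6 and 3 without ox-LDL replicate 3. DCUN1D3, a co-factor of cullin neddylation, rose 3.05-fold and UBE2M, the NEDD8-conjugating enzyme, 1.78-fold. The list median of 0.10 turned to -0.01 with upper-quartile factors and -0.12 with library size alone (camera adjusted p = 0.46 with the main scaling).

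Targets of NRF2, the transcription factor that a cullin 3 ligase marks for degradation, rose in 18 of 22 cases, and BLVRB fell (median 1.12, camera adjusted p = 1.47e-06; adjusted p = 0.19 with an estimated correlation). The thioredoxin reductase gene TXNRD1 went from 279 ± 10.6 to 1931 ± 129 CPM and the cystine transporter gene SLC7A11 from 30.3 ± 0.377 to 233 ± 39.7 CPM. GCLC, the catalytic subunit of the enzyme that starts glutathione synthesis, rose 2.76-fold. NQO1, another member, showed a log2 fold change of 0.17 ± 0.09 and did not pass (adjusted p = 0.14).

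Hypoxia response genes, whose activator HIF is degraded through a cullin 2 ligase, rose in 16 of 19 cases and none fell (median 1.29, camera adjusted p = 1.38e-06; adjusted p = 0.29 with an estimated correlation), though 1 fell with library size alone or without MLN4924 replicate 1. NDRG1 rose 7.12-fold to 458 ± 71.9 CPM, the transcriptional repressor gene BHLHE40 5.56-fold, the glycolytic enzyme gene HK2 5.05-fold and PFKFB4, which regulates glycolysis, 3.53-fold.

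Other stress genes rose as well. Of 19 genes of the unfolded protein and amino acid stress response 15 rose and PDIA4 fell (median 0.81, camera adjusted p = 2.28e-04; adjusted p = 0.48 with an estimated correlation); with upper-quartile factors or library size alone 2 fell. The transcription factor genes CEBPB and ATF3 rose 2.91-fold and 2.82-fold, and the endoplasmic reticulum co-chaperone gene DNAJB9 2.81-fold. PPP1R15A, which restores translation after stress, rose 1.78-fold. HSPA5, the main chaperone of the endoplasmic reticulum, was at 0.09 ± 0.09 and did not pass. Of 16 immediate early and heat shock genes 12 rose and FOS fell 2.48-fold (median 0.63, camera adjusted p = 0.0019; adjusted p = 0.44 with an estimated correlation), with EGR1 up 4.35-fold, the phosphatase gene DUSP1 2.71-fold and JUN 2.16-fold. Adjusted over the list alone 12 rose and 2 fell, and 2 also fell with upper-quartile factors, library size alone and limma-voom, among other settings.

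Autophagy and lysosome genes rose in 15 of 20 cases, and UVRAG fell (median 0.50, camera adjusted p = 2.28e-04; adjusted p = 0.44 with an estimated correlation), or 11 rose and 3 fell with library size alone, and no member fell with a variance weight for each group. The lysosomal protease gene CTSB went from 1026 ± 6.48 to 2630.2 ± 190.2 CPM. ATP6V1H, a subunit of the proton pump that acidifies lysosomes, rose 2.91-fold, the alpha-galactosidase gene GLA 2.88-fold and the autophagosome gene WIPI1 4.50-fold.

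Inflammatory genes controlled by NF-kB rose in 10 of 22 cases and fell in 4, namely NFKBIA, NFKB1, ICAM1 and TRAF1 (median 0.58, camera adjusted p = 0.026; adjusted p = 0.44 with an estimated correlation). The cytokine gene IL1B went from 224 ± 20.3 to 2065 ± 128 CPM (log2 fold change 3.21 ± 0.10) and the neutrophil chemokine gene CXCL8 from 188 ± 22.9 to 1769 ± 245 CPM (3.24 ± 0.12). IER3 rose 5.03-fold and TNFAIP2 2.32-fold. NFKBIA, the inhibitor that NF-kB itself induces, had a log2 fold change of -0.77 ± 0.09. TNF stood at 0.58 ± 0.39 from about 1 CPM and did not pass. The interferon response list did not differ as a set (median -0.39, camera adjusted p = 0.36): 4 of 22 rose, among them OAS2, IFI6 and IRF7, 8 fell and 10 did not pass. With library size alone 2 rose and 8 fell, and with a variance weight for each group 3 rose and 5 fell. USP18, which dampens interferon signaling, fell 1.62-fold.

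Matrix remodelling genes rose in 13 of 19 cases, while MMP2, MMP8, ADAMTS4 and ADAM17 fell (median 0.71, camera adjusted p = 0.0022; adjusted p = 0.25 with an estimated correlation); 2 fell with a variance weight for each group. The macrophage elastase gene MMP12 went from 1.08 ± 0.330 to 36.3 ± 0.750 CPM and MMP7 from 14.7 ± 1.39 to 105 ± 17.9 CPM. PLAU, the urokinase plasminogen activator, rose 5.25-fold. TIMP3, an inhibitor of metalloproteinases, rose 4.87-fold to 458 ± 4.11 CPM.

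Markers of macrophage state did not move as sets. Among 21 monocyte and macrophage identity genes 7 rose and 9 fell (median -0.14, camera adjusted p = 0.65; the median was 0.12 without MLN4924 replicate 2). The counts were 6 and 13 without MLN4924 replicate 1, 9 and 9 without MLN4924 replicate 2, and 7 and 7 without ox-LDL replicate 2. FCGR3A, the low-affinity immunoglobulin receptor CD16, fell 5.63-fold and the lipopolysaccharide co-receptor gene CD14 fell 2.42-fold from 251 ± 3.43 CPM. Among 15 alternative activation genes 7 rose, while MRC1, CD163, KLF4 and STAT6 fell; adjusted over the list alone, 7 rose and 5 fell. TGM2 rose from 42.0 ± 2.15 to 728 ± 72.2 CPM and KLF4, a transcription factor of alternatively activated macrophages, fell from 114 ± 6.93 to 6.27 ± 1.18 CPM. The median of that list was 0.12 and its mean -0.23, camera's direction was up (adjusted p = 0.67), and the median was -0.10 with library size alone and -0.0033 with no low-count filter.

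Mitosis genes fell in 19 of 20 cases with a median log2 fold change of -3.89 (camera adjusted p = 2.89e-10; adjusted p = 0.16 with an estimated correlation). MKI67 went from 124 ± 7.57 to 2.95 ± 0.128 CPM, TOP2A from 69.5 ± 2.31 to 1.5 ± 0.288 CPM, the kinetochore gene CENPF from 44.7 ± 1.92 to 1.92 ± 0.0696 CPM, and CDC20, which activates the anaphase-promoting complex, from 88.2 ± 3.79 to 8.11 ± 1.23 CPM. AURKA was the exception and rose (0.69 ± 0.12). DNA replication genes fell in 21 of 24 cases and none rose (median -1.75, camera adjusted p = 6.68e-10; adjusted p = 0.12 with an estimated correlation). The replicative helicase genes MCM3 and MCM7 fell 4.02-fold and 3.20-fold, UHRF1, which maintains DNA methylation, fell 4.51-fold, and the helicase cofactor gene CDC45 fell 23.4-fold. The members not past the test were MCM6, CCNE1 and SLBP.

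Targets of p53 went both ways, with 7 of 19 higher and 9 lower (median -0.24, camera adjusted p = 0.65), or 7 and 7 with a variance weight for each group. The kinase gene PLK3 rose 3.24-fold and PHLDA3, which restrains AKT signaling, fell 3.57-fold. The cell cycle inhibitor gene CDKN1A had a log2 fold change of 1.29 ± 0.12. Of 21 apoptosis genes 7 rose, BID, CASP8, BIK and APAF1 fell, and 10 did not pass; with upper-quartile factors 7 rose and 8 fell, and with library size alone 6 and 9. BMF, which promotes cell death, rose 4.57-fold and CFLAR, which blocks caspase 8 activation, rose 2.97-fold. The list's median was -0.16, its mean 0.14 and camera's direction up (adjusted p = 0.67).

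Markers of other cell types were mostly at or near 0 counts. Of 12 T and B cell markers only NKG7 and GNLY had enough counts to test, and neither passed; 1 marker of 3 tested fell with libraries thinned to the lowest total, 1 of 4 rose without MLN4924 replicate 2, and 1 rose and 1 fell of 10 with no low-count filter. Among stromal, endothelial and epithelial markers 5 of 16 were testable: VWF rose 3.10-fold to 32.3 ± 0.611 CPM, COL1A1 rose with a log2 fold change of 1.93 ± 0.35, and KDR fell 5.83-fold from 1.97 ± 0.218 CPM. That list's median was 1.08 and camera's direction up (adjusted p = 0.72), fry's direction was down, and the median was -0.25 without MLN4924 replicate 2 and -0.06 with no low-count filter. The neutrophil granule genes ELANE, PRTN3 and AZU1, the 3 testable erythroid and granulocyte markers of 12, rose while the mitosis genes fell. ELANE rose 2.17-fold and PRTN3 1.72-fold. The list missed the threshold (median 0.79, camera adjusted p = 0.064, and 0.48 with an estimated correlation), and its median was 0.83 without MLN4924 replicate 2.

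Mitochondrially encoded messenger RNAs made up 3.44% to 4.17% of the counts in all 5 libraries. Among the 13 genes MT-ND2 (0.28 ± 0.09, adjusted p = 0.024) and MT-CO2 (0.29 ± 0.11, adjusted p = 0.043) passed over all genes tested, and 0 passed when adjusted over the list alone. Both calls were lost when any of the 3 ox-LDL libraries was left out, with adjusted p up to 0.15 for MT-ND2 and 0.23 for MT-CO2. No member rose with upper-quartile factors or with library size alone, where 1 fell, while 10 of the 13 rose without MLN4924 replicate 1 and 4 without MLN4924 replicate 2 or with DESeq2's Wald test. The list median was 0.13 (camera adjusted p = 0.22), turned to -0.09 with library size alone, and passed without MLN4924 replicate 1 (0.24, adjusted p = 0.0499).

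**Figure D3:**
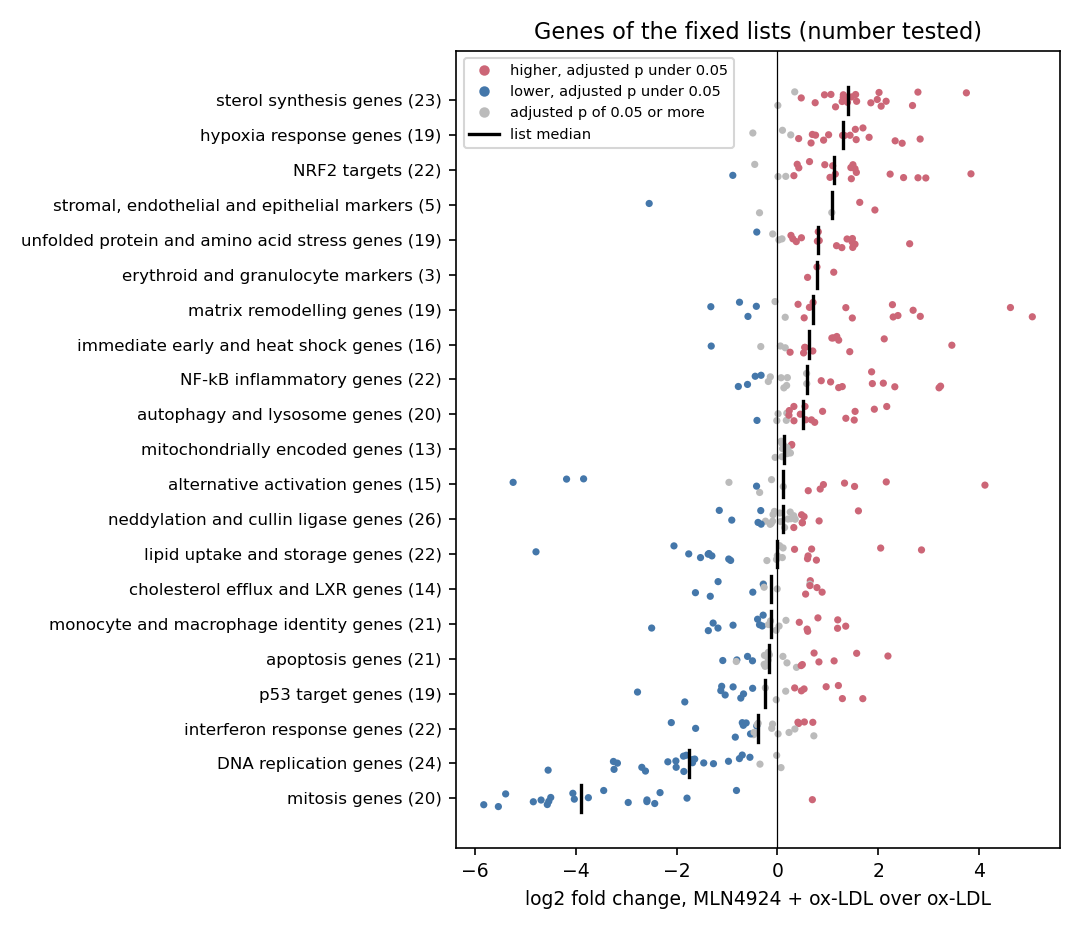
Log2 fold change of MLN4924 with ox-LDL over ox-LDL alone (horizontal axis) for the genes of 21 gene lists fixed before the data were examined, with 1 point per tested gene and the number tested in parentheses. Red and blue points passed adjusted p under 0.05 over all genes, gray points did not, and black bars are list medians, from -3.89 for mitosis genes to 1.40 for sterol synthesis genes; the medians of lipid uptake, neddylation, alternative activation and mitochondrially encoded genes change sign under at least 1 other scaling.

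Adjusted over the list alone, the counts of rises and falls equalled those over all genes except where given above and for the stromal, endothelial and epithelial list, with 3 rises and 1 fall. Of the 77 genes named by rule, 10 share their position with another gene that had at least 10% of their counts, and as the counting's use of strand was not given, their reads may be incomplete or mixed; among them are TGM2, PFKFB4, NPC1, STARD4, MCM7, DNAJB9, DCUN1D3, WIPI1 and NEDD8.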

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

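The fits on protein-coding genes, without mitochondrially encoded genes, with GC content and gene length trends removed and with group weights were chosen after the data were seen. The number of changed genes was 6301 to 8990 over the other scalings, filters, tools and left-out libraries at the same threshold, and 6145 at a threshold of 0.01; no call in any of these fits had the opposite direction to a call in the main analysis. With a variance weight for each group (mean weight 1.77 for the ox-LDL and 0.426 for the MLN4924 libraries) limma-voom called 2661 genes lower and 3640 higher, against 3974 and 4207 without weights. The replicate number did not pair the libraries (correlation of deviations 0.01 for number 1 and -0.02 for number 2). As a block it left 7286 changed genes and 0 of 13 mitochondrially encoded ones. For the integrin gene ITGA1, edgeR's adjusted p was 5.70e-140 in that fit and 7.35e-217 without the low-count filter. It was 1.15e-09 in the main fit. The p-values of these 2 alternatives may therefore be too low and their counts of calls too high. Leaving out a library gave 6799 to 8990 changed genes and 10 to 11 gene lists. The gap between the lowest correlation within groups and the highest between them was 0.0572 and widened to 0.0657 with a prior count of 0.5; its cause was not tested. The list medians do not depend on the list test, and of the 10 lists that passed, 0 did so with an estimated correlation: NRF2 targets (median 1.12, adjusted p = 0.19), NF-kB genes (0.58, 0.44), hypoxia (1.29, 0.29), sterol synthesis (1.40, 0.29), DNA replication (-1.75, 0.12), mitosis (-3.89, 0.16), unfolded protein and amino acid stress (0.81, 0.48), autophagy and lysosome (0.50, 0.44), matrix remodelling (0.71, 0.25), and immediate early and heat shock (0.63, 0.44). With 5 libraries each estimate of a correlation is itself uncertain. The estimate was -0.0015 for DNA replication and 0.012 for matrix remodelling, so the calls of these lists were not lost through a high correlation. The few residual degrees of freedom in that setting can remove a call without one. By fry, 16 lists passed, adding downward cholesterol efflux (-0.13, adjusted p = 0.019), lipid uptake (-0.0093, 0.014), interferon response (-0.39, 0.042), and upward neddylation (0.10, 0.0496), apoptosis (median -0.16, mean 0.14, 0.013) and the granulocyte markers (0.79, 0.014). By camera, the granulocyte markers also passed with upper-quartile factors (0.67, adjusted p = 0.043) and with library size alone (0.57, 0.029), but not with an estimated correlation (adjusted p = 0.48). Over left-out libraries their median was 0.72 to 0.84, and that of the mitochondrially encoded genes was 0.035 to 0.24. Of 1461 alternative values of single named genes, 1439 kept direction and side of the threshold, 13 lost the call (MT-ND2, MT-CO2, UBA3), 9 gained one (NAE1, NEDD8) and 0 reversed. Most named genes were chosen for a large change or a low p-value in these data, so their stability says little about a typical call. Of all calls in the main analysis, 76.2% remained with a variance weight for each group and 89.2% with DESeq2's Wald test. With all libraries thinned to the lowest total, which removed few counts, 98.4% of the calls remained.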

Other observations

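The gene families in this paragraph and the next were chosen after the data were seen, and their directions held under the 4 scalings unless stated. Further families were examined and are not described in detail. With the main scaling, 11 of 49 F-box protein genes rose and 14 fell, and 5 of 12 KLF factor genes rose and 5 fell. Of 28 kinesin genes 6 rose and 17 fell, and 0 of 4 metallothionein genes were called. Subunits of the V-type ATPase, the proton pump of lysosomes and endosomes, rose in 15 of 18 cases and ATP6V0E2 and ATP6V1E2 fell (median log2 fold change 0.66; adjusted p = 0.0995 for ATP6V1E2 with a variance weight for each group), with ATP6V1B2 going from 357 to 773 CPM. Integrin subunits, which bind matrix and other cells, rose in 13 of 23 cases and fell in 6: ITGA1 went from 0.654 to 45.3 CPM, ITGA2 from 11.1 to 104 CPM and the fibronectin receptor subunit ITGA5 from 829 to 2050 CPM, while the leukocyte integrin ITGAL fell from 557 to 150 CPM (log2 fold change -1.89 ± 0.10). Among sphingosine-1-phosphate receptors S1PR1 fell from 702 counts over the 3 ox-LDL libraries to 5 over the 2 MLN4924 libraries, while S1PR3 rose from 158 to 990 counts. Among chemokine receptors CX3CR1 fell from 22.4 ± 1.34 to 0.673 ± 0.587 CPM (log2 fold change -5.06, or -6.40 and -4.34 without MLN4924 replicate 1 and 2) and CXCR4 rose from 1.98 to 17.3 CPM. The endotoxin receptor TLR4 fell (-2.26 ± 0.09), TLR8 had 709 and 2 counts and TLR7 323 and 1 counts in the 2 groups, and TLR2 was at -0.04 ± 0.08 and did not pass, but was lower with library size alone (-0.26, adjusted p = 0.011).

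Of 10 tested FANC genes, which repair DNA crosslinks, 7 fell and FANCE rose; 4 fell with a variance weight for each group. Polyadenylated transcripts of histone genes rose in 9 of 19 cases, and HIST1H1C fell, though not with a variance weight for each group (adjusted p = 0.097). All 5 tested HLA class I genes rose (median 0.49), though 2 did so with library size alone. Guanylate-binding protein genes GBP1, GBP2 and GBP3 fell, GBP1 from 19.7 to 2.85 CPM; GBP3 (-0.40) did not pass without ox-LDL replicate 1 or 3, with trends in GC content and gene length removed (-0.24, adjusted p = 0.086) or with group weights. Cytosolic ribosomal protein genes fell in 31 of 83 cases and 1 rose (median -0.28), but the count depended on the scaling and on the libraries. There were 55 falls with upper-quartile factors, 71 with library size alone, 76 without MLN4924 replicate 1 and 16 to 18 without any 1 of the ox-LDL libraries, and without MLN4924 replicate 2 23 fell and 16 rose.

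For the patterns below, the tests of scale, of depth, of counts near the floor, of undifferentiated cells and of the LXR targets were chosen after the values they use had been seen. More than 50% of the tested genes changed in the main analysis (8229 of 15558). Some settings called less than 50%, such as DESeq2's Wald test (7376) and a variance weight for each group (6301), and others called more, such as library size alone (8892). A plain offset in scale moves every gene alike and so cannot by itself change many genes 2-fold in both directions, yet the rarer direction held at least 1211 genes changed that much under each of the 4 scalings. A difference in depth is argued against by the mean totals of the groups, which differed by 3.31%. A broad effect of MLN4924 stays open as a hypothesis.

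The mitosis genes fell together by a median of 3.89 on the log2 scale. Low counts do not account for it: the 17 members with a mean log2 CPM of at least 3 in the ox-LDL libraries had a median of -4.03, the 10 that reach it over all libraries -3.02, and removing trends with GC content and gene length left the list at -3.77. A smaller share of undifferentiated, dividing THP-1 cells in the MLN4924 libraries would be expected to lower the granule genes ELANE, PRTN3 and AZU1. Their median was 0.79, with each above 0 by more than 2 SE. Only 3 genes bear on this, and they were chosen after their rise had been seen. Whether MLN4924 itself moved them was not tested, so these values do not decide the question. Fewer cycling cells of the same differentiation state, by arrest or by loss, is a candidate explanation that was not tested.

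Sterol synthesis genes rose while CD36, FABP4 and PLIN2 fell. Trends with GC content and gene length are argued against: with them removed, the sterol synthesis median was 1.44 and CD36, FABP4 and PLIN2 stood at -1.28, -1.95 and -1.37. Lower PPAR activity was tested on 15 other PPAR target genes whose values had not been seen: 8 fell and 2 rose, with a median of -0.52 (camera p = 0.023, and p = 0.30 with an estimated correlation), which is consistent with that hypothesis but weak. Lower LXR activity could not be decided: 4 of 5 target genes had negative values, SREBF1 and ABCG1 past the test, but ABCA1 rose. A change in the sterol content of the cells may underlie both, and was not measured.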
